A study of Bifidobacterium breve UCC2003 with 5 samples.

How the data were processed

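Total RNA of *Bifidobacterium breve* UCC2003 was compared on 5 two-colour Agilent expression arrays, each of which carried cDNA of chelator-grown cells in one dye and cDNA of cells from untreated medium in the other. The labels give 2 arrays with ciclopirox olamine at 85 µM, 2 arrays with phenanthroline at 100 µM and 1 array with dipyridyl at 275 µM, all from cells harvested at an OD600 of 0.6 after anaerobic growth at 37 °C in filtered reinforced clostridial medium. Within the ciclopirox olamine and the phenanthroline pair the dyes were swapped, with the treated cells in Cy5 on replicate 1 and in Cy3 on replicate 2. The dipyridyl array had the treated cells in Cy5.

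Spot and local background intensity were taken from the deposited scanner output, which carries no normalization in these columns. The processed intensity columns were background-subtracted and dye-normalized within each array by Agilent Feature Extraction, per the file headers. The log10 ratio column of the same files is the log10 of processed Cy5 over processed Cy3, per the file headers, and it equalled the ratio of the processed columns on 98.6% to 99.7% of gene spots. The value table deposited by the authors holds the same log10 ratios, rounded. Its values lay within 0.005 of the scanner's log10 ratio of the spot with the same number on every array, with the direction Cy5 over Cy3 and no further centring. The column medians of that table were -0.0015 and 0.0045 for ciclopirox olamine replicates 1 and 2, -0.0009 and 0 for phenanthroline replicates 1 and 2, and 0.0015 for dipyridyl. The software version is 9.5 per the submitters' processing notes, whereas the headers give 11.0.1.1 for the ciclopirox olamine and phenanthroline arrays and 9.1.1.1 for the dipyridyl array.

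The ciclopirox olamine and phenanthroline arrays share one design with 45220 spots, of which 43803 carry 8262 probes of genes. These 4 arrays were scanned together from 1 slide. The dipyridyl array has another design with 10807 spots, of which 10263 carry 5664 probes of genes. Both designs hold 1843 locus tags, 20 tRNA features and 1 feature for 16S rRNA, together 1864 genes, of which 1862 are on both. The designs also carry 21 and 17 plasmid, vector or unplaced features and 7 spike features, which were left out of all tests. The files do not pair the locus tags with gene names or products. The reference table supplied for the organism describes another assembly, and 0 of the 1843 tags were found in it. The 20 gene lists fixed before the data were examined, among them iron transport and bile salt hydrolase, are defined by names or products, had 0 members found and were not analysed here. Transfer RNAs, which the files do name, were analysed as a group. Loci are therefore given by tag, at most 2 higher and 2 lower in each comparison.

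Background was corrected with normexp at an offset of 50, on median spot signals for the ciclopirox olamine and phenanthroline arrays, whose files hold no mean signals, and on mean spot signals for the dipyridyl array. Log ratios were normalized by loess within each array with control spots at weight 0. Control spots and spots flagged by the scanner software as non-uniform or as population outliers were then left out, which removed 0.283% to 3.15% of gene spots per array. No gene spot was saturated. Each array's log2 ratio was turned to treated over untreated by the dyes in the labels. Spots of one probe were averaged, then the probes of one gene. No filter was set on dim genes. Probes of 6 genes shared a sequence with another gene, and none of these genes is named in the text.

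A linear model with 1 coefficient for ciclopirox olamine and 1 for phenanthroline was fitted to the 4 dye-swapped arrays with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation of the variance. The fit left 2 residual degrees of freedom, and the prior contributed 4.18 more with a prior SD of 0.180. A gene was called when its Benjamini-Hochberg adjusted p over the 1864 genes was under 0.05, and all tests were two-sided. The contrast of the coefficients tested the difference between the chelators. The dipyridyl array has no replicate and a single dye orientation, so its ratios are given without a test, counted at 3-fold, the size criterion of the study. On simulated ratios with 200 changed genes among 1864, over 20 rounds with the spread of the real arrays, the model recovered 99.6% of 2-fold changes with ciclopirox olamine and 99.4% with phenanthroline, and false calls made up 5.3% and 5.1% of all calls. The simulation changed far fewer genes than were called in the data, 62.3% and 54.6%. If the spread between the arrays is technical, it also leaves out differences between cultures. These rates are therefore not the error rates of the real calls.

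Named loci are those with the largest positive and negative log2 fold change among called genes that moved the same way on both arrays, those with the largest differences between the chelators among genes whose difference was called, and those with the largest dipyridyl ratios. This rule was fixed before the data were examined for 10 loci per direction, 5 for the difference, and was shortened to 2 because the tags carry no names. The tRNA group was tested with camera at its preset correlation and with an estimated one. Tag numbers were taken as the order of genes. Runs were defined as at least 3 consecutive tag numbers, all called and at least 2-fold changed in one direction, and were compared with 1000 shuffled gene orders. The overlap between the chelators was set beside the overlap of independent lists and beside 200 simulations of unchanged groups measured against 1 shared control.

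The number of arrays limits the precision. The labels do not say whether the arrays of a dye swap came from separate cultures, so the spread between them, on which every adjusted p rests, may be technical. Untreated cells were not compared with each other, so the control's own spread is not seen, and the control RNA may have been the same for several arrays.

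Alternatives covered the background correction, the normalization, the scanner's own log ratios, the value table, the summary over probes, a filter on dim genes, a dye coefficient, the variance prior, the arrays entering the fit, the size threshold and each array left out in turn. The study's own test, a regularised form of the t-test, was run on the same values as the methods' t-test, at the thresholds given in the series description. Median in place of mean signals on the dipyridyl array was added after the data had been seen.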

Results

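Gene expression was measured in *Bifidobacterium breve* UCC2003, a gut bifidobacterium, grown with each of 3 iron chelators relative to growth in the untreated medium. Ciclopirox olamine (a hydroxypyridone) and phenanthroline were measured on 2 arrays each, and dipyridyl on 1 array. Phenanthroline and dipyridyl are both bidentate chelators that bind through nitrogen, with fused rings in phenanthroline and with rings joined by a single bond in dipyridyl. Each array held treated and untreated cells together, and a ratio is always that of treated over untreated cells. The doses differed, at 85 µM for ciclopirox olamine, 100 µM for phenanthroline and 275 µM for dipyridyl.

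Signals were well above background in most spots. In the channel of the treated cells, 99.3% and 99.4% of gene spots were well above background on the ciclopirox olamine arrays, 99.1% and 95.6% on the phenanthroline arrays and 98.8% on the dipyridyl array. In the untreated channel the share ranged from 90.0% on phenanthroline replicate 2 to 98.8% on the dipyridyl array. The median signal of gene spots ranged from 366 to 1382 intensity units in the treated channel and from 233 to 684.5 in the untreated channel.

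The first comparison asks which genes change when growth takes place with ciclopirox olamine. The locus with the largest increase was Bbr_0826, at a log2 fold change of 5.35 ± 0.12 (SD, n = 2), which is 40.9-fold. Bbr_0579 followed at 5.05 ± 0.20 (SD, n = 2), 33.1-fold, and stood at 3.99 with median centring in place of loess. The largest decreases were in Bbr_0417, at -3.22 ± 0.03 (SD, n = 2) or 9.34-fold lower, and in Bbr_0106, at -3.21 ± 0.52 (SD, n = 2) or 9.24-fold lower. Each of these loci moved the same way on both arrays, with limma adjusted p-values of 3.52e-05 for Bbr_0826, Bbr_0579 and Bbr_0417 and 6.04e-05 for Bbr_0106.

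Of 1864 genes, 638 were higher and 524 lower with ciclopirox olamine, 62.3% of all genes. The normalization centred each array's ratios on its own genes, so higher and lower are relative to the typical gene, here and below. A shift of most genes in one direction would not be seen. With this many genes called, the balance of higher and lower genes follows in part from the centring. At least 2-fold changes were seen in 276 of the higher and 179 of the lower genes, and at least 3-fold changes in 132 and 49. The 1162 called genes all moved the same way on both arrays. The call itself requires this, because arrays of opposite sign give too large a spread to pass, so it is no measure of reproducibility. In 88.6% of the called genes every probe had the same sign. For 4 genes no probe was well above background in the untreated channel. The methods' t-test at the study's thresholds gave 132 higher and 47 lower genes. Without replicate 2 the counts fell to 419 higher and 340 lower.

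Changed genes lay next to each other. Among the 272 locus tags at least 2-fold higher with ciclopirox olamine, 75 formed 17 runs of consecutive tags, the longest of 8 tags, where shuffled gene orders gave at most 12 runs. Among the 178 tags at least 2-fold lower, 54 formed 14 runs, against at most 6 in shuffled orders. The permutation p was 0.001 in both directions, the smallest that 1000 shuffles can give. A run of 4 tags beginning at Bbr_0106 had a median log2 fold change of -2.67, 6.37-fold lower, and a run of 4 tags beginning at Bbr_0417 one of -1.72, 3.30-fold lower.

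The second comparison asks the same of phenanthroline. Bbr_0826 again had the largest increase, at a log2 fold change of 5.81 ± 0.60 (SD, n = 2) or 56.3-fold, and Bbr_0579 rose by 4.84 ± 0.36 (SD, n = 2), 28.6-fold. The largest decreases were again in Bbr_0417, at -4.16 ± 0.11 (SD, n = 2) or 17.9-fold lower, and in Bbr_0106, at -3.90 ± 0.12 (SD, n = 2) or 15.0-fold lower. The limma adjusted p was 2.55e-05 for Bbr_0826, Bbr_0579 and Bbr_0417 and 3.27e-05 for Bbr_0106. From the scanner's processed signals and its log ratios Bbr_0106 stood at -4.82 and -4.89, below Bbr_0417 at -4.72 and -4.84.

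With phenanthroline 501 genes were higher and 517 lower, 54.6% of the 1864 genes. At least 2-fold changes were seen in 239 and 175 of them, and at least 3-fold changes in 130 and 62. The 1018 called genes all moved the same way on both arrays, which the call again requires, and every probe had the same sign in 96.8% of them. For 11 genes no probe was well above background in the untreated channel. The methods' t-test at the study's thresholds gave 130 higher and 61 lower genes.

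Runs of neighbouring tags were found here too. Of 239 tags at least 2-fold higher, 90 formed 23 runs, against at most 10 in shuffled orders, and of 172 tags at least 2-fold lower, 58 formed 15 runs, against at most 6 (permutation p = 0.001 for each, the smallest possible). The run of 4 tags beginning at Bbr_0106 had a median log2 fold change of -3.02, 8.09-fold lower, and that beginning at Bbr_0417 one of -2.35, 5.08-fold lower. Across all 1778 pairs of consecutive tags, the fold changes of neighbours correlated at r = 0.452 with phenanthroline and 0.423 with ciclopirox olamine, where the highest value of the shuffled orders was 0.0797 and 0.0782. These correlations are across genes, which are not independent replicates.

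**Figure D1:**
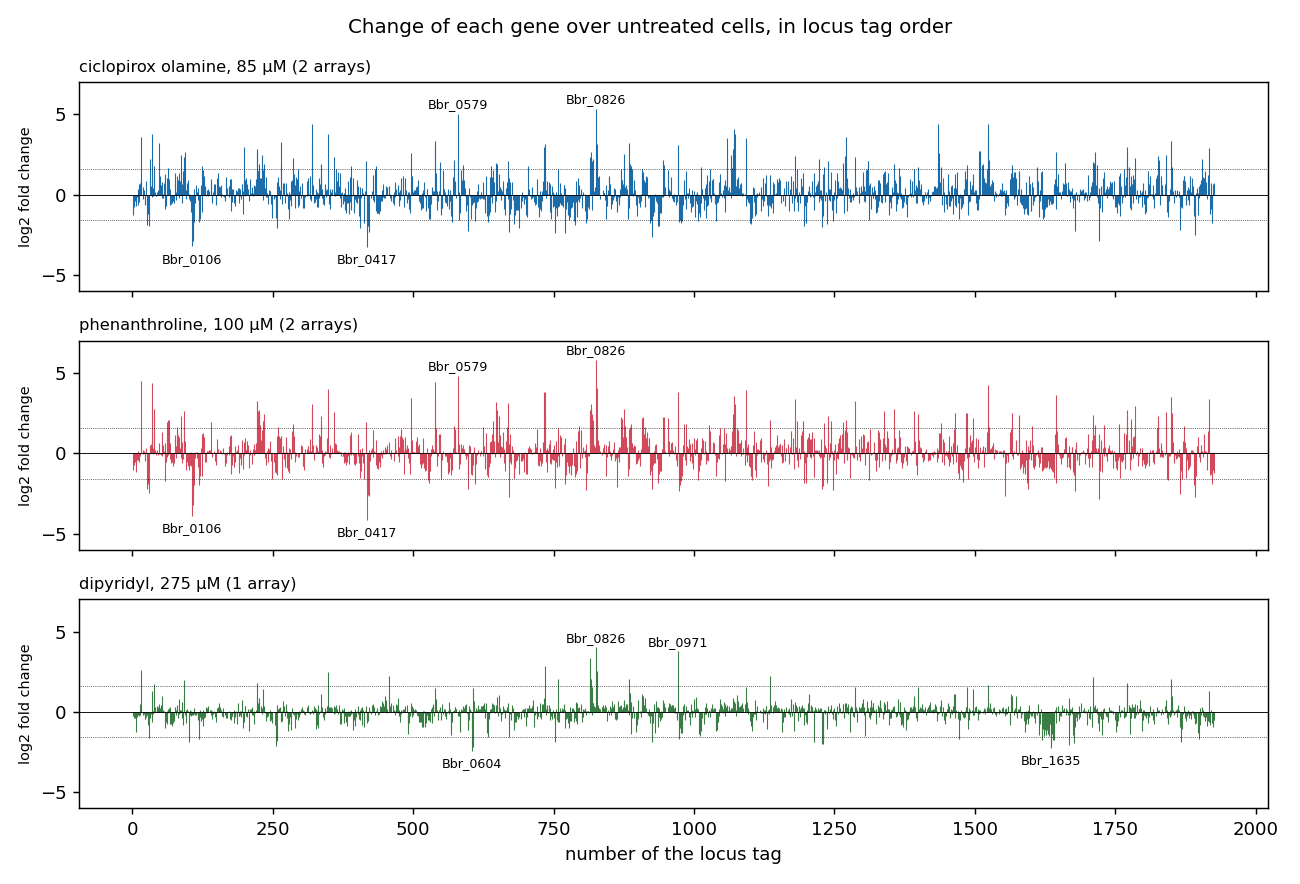
Log2 ratio of treated over untreated cells (vertical axis) of each locus tag against its tag number (horizontal axis), for ciclopirox olamine and phenanthroline as means of 2 arrays and for dipyridyl as 1 array. Neighbouring tags often lie at similar heights, and Bbr_0826 stands highest in each panel, at 5.35, 5.81 and 4.04, although with dipyridyl Bbr_0971 stands higher from the scanner's processed signals (3.68 against 3.48) and without background subtraction (3.59 against 3.22).

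The chelators were then compared with each other, at their different doses. Of the genes tested, 377 were higher and 377 were lower with both ciclopirox olamine and phenanthroline, where independent lists of the same lengths would share 171.5 and 145.3. Bbr_0826 differed between the chelators by -0.46 on the log2 scale, ciclopirox olamine minus phenanthroline, with a 95% interval from -1.16 to 0.24 and a limma adjusted p of 0.285. For Bbr_0579 the difference was 0.21, with an interval from -0.33 to 0.75 and an adjusted p of 0.523. Bbr_0417 fell by less with ciclopirox olamine, with a difference of 0.94, an interval from 0.56 to 1.32 and an adjusted p of 0.0122.

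Other loci differed between the chelators by more. Bbr_1435 rose with ciclopirox olamine by 4.38 ± 0.18 (SD, n = 2), 20.9-fold (adjusted p 2.81e-05), and stood at 0.20 ± 0.02 with phenanthroline (adjusted p 0.199). The difference was 4.18 (95% interval 3.79 to 4.58, adjusted p 0.000314), and 5.25 with the median over probes, outside that interval. Bbr_1058 rose with ciclopirox olamine by 3.54 ± 0.24, 11.6-fold, and stood at 0.34 ± 0.01 with phenanthroline (adjusted p 0.0578), a difference of 3.20 (2.77 to 3.62, adjusted p 0.00125). Its untreated signal was well above background in 93.9% of probe spots on the ciclopirox olamine arrays and in 73.9% on the phenanthroline arrays. In the other direction, Bbr_1485 rose by 2.53 ± 0.32, 5.76-fold, with phenanthroline (adjusted p 4.31e-05) and by 0.97 ± 0.11 with ciclopirox olamine (adjusted p 0.00153), a difference of -1.56 (-2.05 to -1.07, adjusted p 0.00834). Bbr_0233 rose by 1.13 ± 0.28 with phenanthroline and stood at -0.30 ± 0.14 with ciclopirox olamine (adjusted p 0.103), a difference of -1.42 (-1.89 to -0.95, adjusted p 0.00872).

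In all, the difference between the chelators was called for 405 genes, 227 higher and 178 lower with ciclopirox olamine than with phenanthroline, which is 21.7% of the genes. At least 2-fold differences made up 118 of the higher and 34 of the lower genes, at least 3-fold differences 36 and 0. The count of 0 by limma was also 0 at an unadjusted p under 0.05, and the methods' t-test after Benjamini-Hochberg adjustment gave 1 gene. Of the genes called with ciclopirox olamine alone, 367 in number, the difference was called for 136, and of the 223 called with phenanthroline alone for 86. Opposite calls were made for 30 genes higher with ciclopirox olamine and lower with phenanthroline and for 11 genes the other way round, and the difference was called for each of them. For 1260 genes, 67.6%, the 95% interval of the difference lay within 2-fold in both directions. The 114 tags at least 2-fold higher with ciclopirox olamine than with phenanthroline included 6 runs with 19 tags, against at most 3 runs in shuffled orders (permutation p = 0.001, the smallest possible), and the 34 lower ones none.

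The count of differing genes depended on single arrays and on the model. Without ciclopirox olamine replicate 1 it was 173 (129 higher and 44 lower with ciclopirox olamine than with phenanthroline), without ciclopirox olamine replicate 2 it was 117 (93 and 24), and with a dye coefficient it was 849 (426 and 423). Without phenanthroline replicate 1 the higher genes numbered 213 and the lower ones 95, and without phenanthroline replicate 2 they numbered 213 and 226, so that the balance turned. In the fit with a dye coefficient, the limma adjusted p of 16S rRNA with ciclopirox olamine was 4.2e-74, although its arrays read -0.63 and -4.02. That fit takes too small a spread for such genes, so its counts are not reliable. With median centring in place of loess, 41.4% of the differing genes were higher with ciclopirox olamine, against 56.0% with loess.

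Fold changes of the chelators correlated across the 1864 genes at r = 0.809 (Spearman's rho 0.751, covariance 0.778), and r between single arrays of different chelators ranged from 0.762 to 0.812. Arrays of the same chelator correlated at 0.948 for ciclopirox olamine and 0.935 for phenanthroline. Simulated groups without any change, measured against 1 shared control, gave r = 0.399 and a covariance of 0.0420. The simulation drew its noise from the spread between arrays, which may be technical, and held no spread between cultures. Both values may thus be too small for a shared control, and they set no upper limit on its part. The labels do not say whether the control RNA was shared, and the controls cannot be split, so part of the overlap may come from it.

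**Figure D2:**
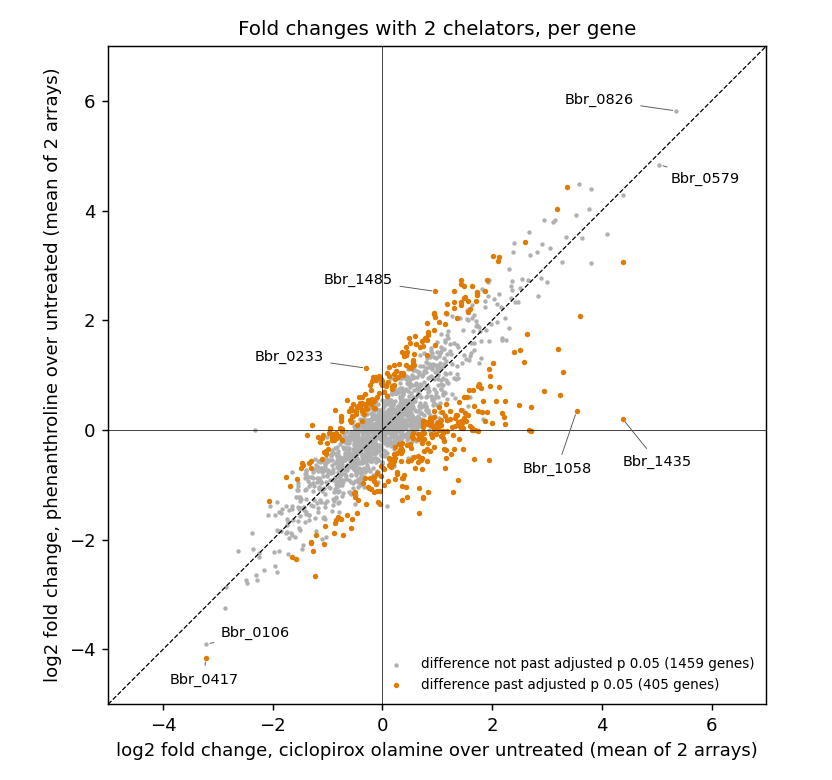
Mean log2 fold change of each gene with phenanthroline (vertical axis) against that with ciclopirox olamine (horizontal axis), 2 arrays each, with the genes whose difference was called in colour and the named loci labelled. Bbr_0826 and Bbr_0579 lie high and Bbr_0417 and Bbr_0106 low on both axes, whereas Bbr_1435 and Bbr_1058 lie high on the ciclopirox olamine axis and at 0.20 and 0.34 on the other.

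The dipyridyl array asks whether the changes extend to a further chelator. Bbr_0826 and Bbr_0971 had the largest ratios, at log2 values of 4.04, 16.4-fold, and 3.78, 13.8-fold. Their order turned from the scanner's processed signals (3.48 for Bbr_0826 and 3.68 for Bbr_0971) and without background subtraction (3.22 and 3.59), and with median centring in place of loess they stood at 3.40 and 2.25. Bbr_0971 was also higher with ciclopirox olamine, by 3.10 ± 0.03 (SD, n = 2, adjusted p 5.37e-05), and with phenanthroline, by 3.80 ± 0.42 (SD, n = 2, adjusted p 2.98e-05). The lowest ratios with dipyridyl were those of Bbr_0604, at -2.42 or 5.35-fold lower, and of Bbr_1635, at -2.27 or 4.82-fold lower. Across the settings these values ranged from -1.70 (processed signals) to -2.94 (median centring) for Bbr_0604 and from -1.59 to -2.79 for Bbr_1635. Bbr_0604 was lower with phenanthroline, at -1.34 ± 0.17 (SD, n = 2, adjusted p 0.000191), and stood at -0.05 ± 0.05 with ciclopirox olamine (adjusted p 0.709; difference between the chelators 1.29, adjusted p 0.00834). Bbr_1635 was lower with both, at -0.45 ± 0.29 with ciclopirox olamine (SD, n = 2, adjusted p 0.0346) and -0.89 ± 0.20 with phenanthroline (SD, n = 2, adjusted p 0.0025).

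Several loci that led the other comparisons had small ratios with dipyridyl. Bbr_0579 stood at a log2 ratio of -0.27, Bbr_0106 at -0.17 and Bbr_0417 at -0.70, and the runs of 4 tags beginning at Bbr_0106 and Bbr_0417 had median ratios of -0.14 and -0.54. Bbr_1435 stood at -0.16 and Bbr_1058 at 0.45.

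On the dipyridyl array 23 genes were at least 3-fold higher and 24 at least 3-fold lower, a count of ratios without a replicate or a test. The split depended on the normalization, with 48.9% of these genes higher in the values reported here, 82.6% from the scanner's processed signals with loess, 84.2% without background subtraction, 70.0% from the scanner's own log ratios and 11.4% with median centring in place of loess. Of the 21 genes at least 3-fold higher that both designs measure, 21 were called higher with both other chelators, and of the 24 lower, 16 were called lower with both, 16 with ciclopirox olamine and 23 with phenanthroline. Ratios correlated across 1862 genes at r = 0.629 with phenanthroline and 0.517 with ciclopirox olamine, and their SD was 0.563, against 0.989 and 0.973. Of 84 genes called and at least 3-fold higher with both other chelators, 78 were above 0 with dipyridyl, 32 were at least 2-fold higher and 38 lay within 1.5-fold of no change. Of 33 such lower genes, 29 were below 0, 12 were at least 2-fold lower and 12 lay within 1.5-fold.

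**Figure D3:**
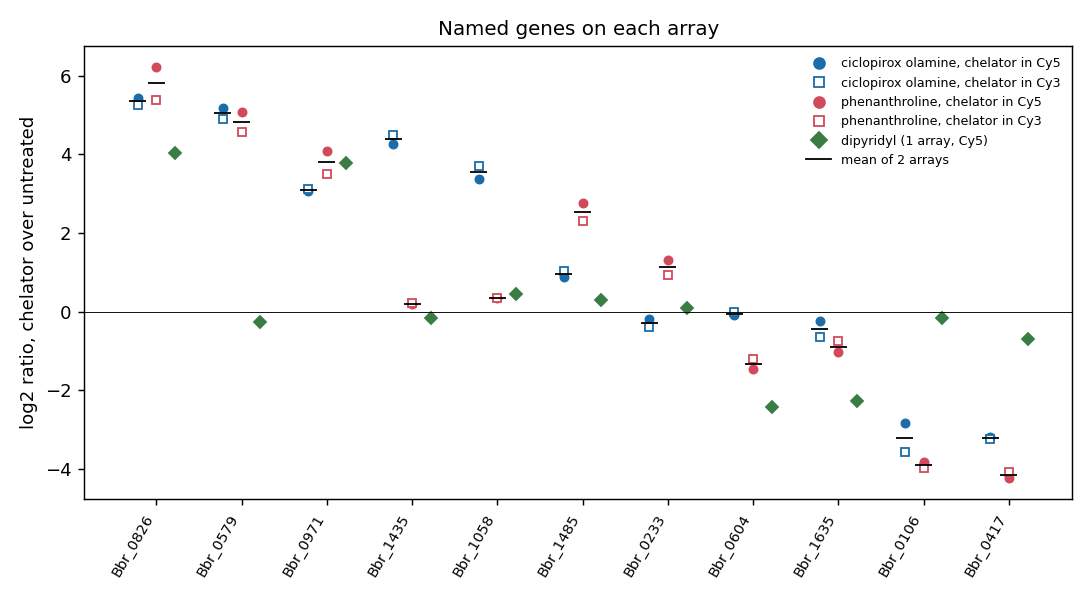
Log2 ratio of treated over untreated cells (vertical axis) of the named loci, with a point for each array and a bar for the mean of the 2 arrays of ciclopirox olamine and of phenanthroline, dipyridyl having 1 array. Bbr_0826 is high with all 3 chelators, whereas Bbr_0579 lies at 5.05, 4.84 and -0.27.

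The balance of higher and lower transfer RNA features depended on the setting with ciclopirox olamine and on 1 array with phenanthroline. With ciclopirox olamine 7 of 20 were higher, 1 was lower and 12 did not pass, beside 638 higher among all 1864 genes. The counts were 10 higher and 6 lower with a dye coefficient, in the fit whose counts are not reliable. They were 9 and 6 by the methods' t-test after Benjamini-Hochberg adjustment and 9 and 5 from the arrays of this chelator alone. With median centring they were 6 and 3, and from the scanner's processed signals and its log ratios 4 and 1. tRNA-Leu rose by 1.95 ± 0.23 (SD, n = 2, adjusted p 0.000958), tRNA-Phe by 1.67 ± 0.07 (adjusted p 0.000387), tRNA-Lys by 1.48 ± 0.30 (adjusted p 0.00218) and tRNA-Trp by 1.13 ± 0.12 (adjusted p 0.0083), whereas tRNA-Thr stood lower at -0.95 ± 0.00 (adjusted p 0.00152). With phenanthroline 0 were higher by limma (0 also at an unadjusted p under 0.05 and by the methods' t-test after Benjamini-Hochberg adjustment), 5 were lower and 15 did not pass. Without phenanthroline replicate 2, 7 were higher and 3 lower, tRNA-Trp (0.85, adjusted p 0.00463) and tRNA-Lys (0.70, adjusted p 0.0213) among the higher, and without phenanthroline replicate 1, 0 were higher and 13 lower. A dye coefficient gave 3 higher and 9 lower, again in the fit whose counts are not reliable. From the scanner's processed signals and without background subtraction, 0 were higher and 3 lower. In the fit of the 4 arrays the lower ones included tRNA-Thr at -1.07 ± 0.32 (adjusted p 0.00102) and tRNA-His at -1.23 ± 0.71 (adjusted p 0.00438). tRNA-Thr stood at -1.98 from the scanner's log ratios, and tRNA-His at -0.73 without phenanthroline replicate 2. The difference between the chelators was called for tRNA-Leu at 2.50 (adjusted p 0.0105), tRNA-Phe at 2.19 (adjusted p 0.00687), tRNA-His at 1.98 (adjusted p 0.012) and tRNA-Lys at 1.26 (adjusted p 0.0431).

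Adjusted over the list alone, 4 tRNA features were higher and 1 was lower with ciclopirox olamine, and 0 were higher and 2 lower with phenanthroline. As a group the 20 features, each with 1 probe on the dye-swapped arrays, had a median log2 fold change of 0.28 with ciclopirox olamine and -0.25 with phenanthroline. The group did not pass against the other genes (camera, adjusted p 0.612 and 0.272, and 0.901 for both with an estimated correlation). The estimated correlation was 0.774, at which this test can hardly detect a shift, so a shift of the group is not excluded. The tRNA ratios of the phenanthroline arrays differed by dye orientation, with a median of 1.06 for replicate 1 minus replicate 2 and a higher ratio on replicate 1 for 19 of the 20 features, against a median of 0.12 with ciclopirox olamine. With ciclopirox olamine, 4 features were higher and 2 lower without replicate 1, and 4 higher and 1 lower without replicate 2. tRNA-His with ciclopirox olamine (0.74, adjusted p 0.0296) lost its call in 6 settings, as with the scanner's log ratio (adjusted p 0.107). tRNA-Phe with phenanthroline (-0.53, adjusted p 0.0408) lost it in 4, as without replicate 2 (-0.19, adjusted p 0.399). The difference for tRNA-Lys lost its call in several settings, with values from 0.78 without phenanthroline replicate 2 to 1.47 without ciclopirox olamine replicate 2.

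**Figure D4:**
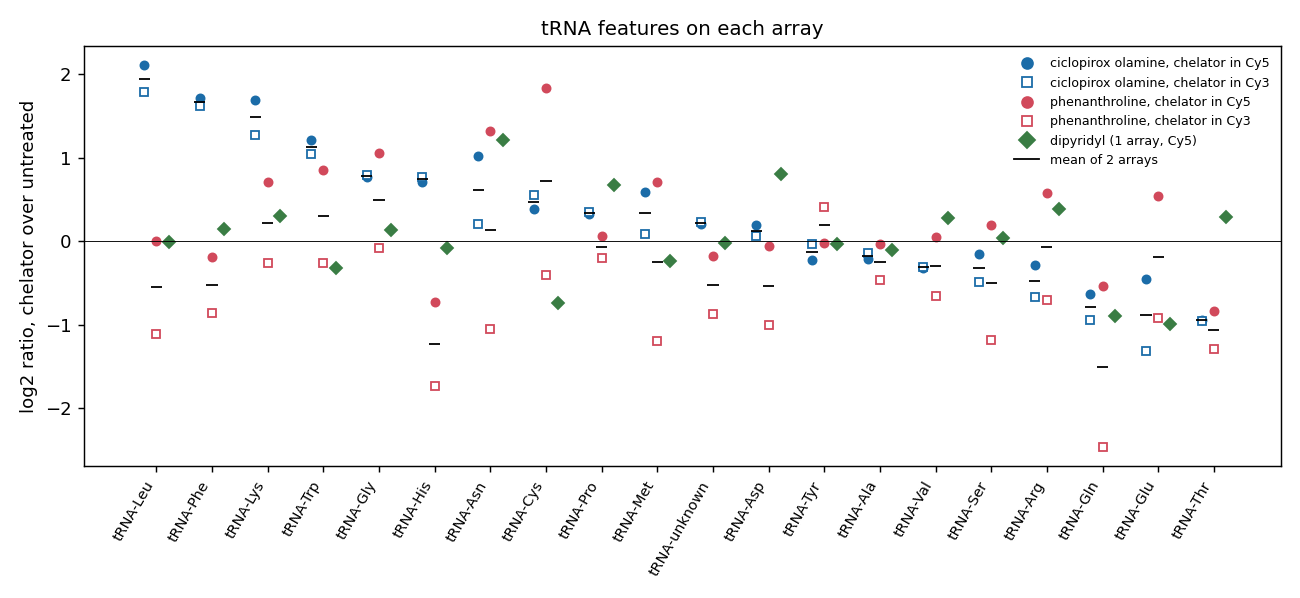
Log2 ratio of treated over untreated cells (vertical axis) of the 20 tRNA features, with a point for each array and a bar for the mean of the 2 arrays of ciclopirox olamine and of phenanthroline. The phenanthroline arrays lie apart by a median of 1.06, the ciclopirox olamine arrays by 0.12.

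The 16S rRNA feature had log2 ratios of -0.63 and -4.02 on the ciclopirox olamine arrays, a mean of -2.33 ± 2.40 (SD, n = 2) with an adjusted p of 0.0274, and the call rested on replicate 2, without which the value was -0.63 with an adjusted p of 0.0804. With phenanthroline it stood at -0.01 ± 0.42.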

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

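The tests of the tRNA probes' dye effect and of the signal floor were chosen after the results had been seen, and the other tests given here were written before.

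The responses to ciclopirox olamine and phenanthroline differed by a test of the difference itself for 405 genes. Among them, 30 genes were higher with ciclopirox olamine and lower with phenanthroline, and 11 were lower with ciclopirox olamine and higher with phenanthroline. On the log2 scale, ciclopirox olamine minus phenanthroline, the difference was 4.18 for Bbr_1435, 3.20 for Bbr_1058, -1.56 for Bbr_1485 and -1.42 for Bbr_0233. For tRNA features it was 2.50 for tRNA-Leu, 2.19 for tRNA-Phe, 1.98 for tRNA-His and 1.26 for tRNA-Lys, whose call was lost in several settings. The chelators were given at different doses, so a difference between compounds and one between doses cannot be separated here. Without ciclopirox olamine replicate 2 the difference was called for 117 genes, and without ciclopirox olamine replicate 1 for 173, with 24 and 44 of them lower with ciclopirox olamine, against 178 with all arrays.

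Outside the genes tested, 1 unplaced feature that the design names only CDS was well above background in both channels on the dye-swapped arrays. Its log2 ratio was 1.57 ± 0.22 (SD, n = 2) with ciclopirox olamine and 0.52 ± 0.84 with phenanthroline, where replicates 1 and 2 read 1.11 and -0.07. The spike features had median ratios between -0.69 and -0.08. They were dim, with a median of the mean log2 intensity of 6.46 against 11.15 for this feature, so they are no baseline for it.

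The many genes higher or lower with each chelator were set against technical sources. GC content was read from the probe sequences of the dipyridyl design, while the fold changes came from the other design. Spearman's rho between the fold change and this GC content was -0.0504 with ciclopirox olamine and -0.0584 with phenanthroline. The fold changes thus hardly followed the GC content of those stretches. The GC content of the probes that gave the calls was not read, so an effect of it stays open. The 20 dim plasmid, vector and unplaced features had a median log2 ratio of -0.62 with ciclopirox olamine and -0.32 with phenanthroline, and a signal floor that differs between the channels would lower dim genes likewise. Of the 296 genes at or below the intensity of the brightest of these features, 15.9% of all genes, the median was 0.12 and 0.07, and they made up 4.58% (24 genes) and 3.87% (20 genes) of the genes called lower. The loess correction centres the ratios of genes at each intensity, so these medians cannot speak against a floor. Most genes called lower were brighter than the brightest of these features, which argues against a floor as the source of most lower calls. Those 24 and 20 genes stay open. A change in the cells due to the chelators is a hypothesis that these tests leave standing; the labels do not say how many cultures were grown.

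The tRNA ratios lay apart by dye orientation with phenanthroline, by a median of 1.06 (quartiles 0.69 to 1.40). A dye effect of the tRNA probes would appear with ciclopirox olamine too, where the median difference was 0.115, and a difference brought in by the loess correction would vanish without loess, where it was 0.857. Both values argue against these sources. Separate RNA preparations with different yields of small RNA could differ in this way, which was not tested. No biological explanation was tested, because both arrays belong to one group.

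Many genes that changed with both ciclopirox olamine and phenanthroline stood near no change with dipyridyl, 50 of 117 genes within 1.5-fold. After the ratios predicted from the other chelators were taken off, neighbouring tags still correlated at 0.263 over all locus tags, above the highest shuffled value of 0.108. What was left on the dipyridyl array was thus not noise of single probes alone. The 50 genes were not taken apart in this test, so it cannot decide whether such noise placed them near no change. After gene-specific dye effects measured on the dye-swapped arrays were taken off, 49 genes lay within 1.5-fold, which argues against a dye effect common to both designs. Dye effects of the dipyridyl array's own probes were not measured, because it has 1 dye orientation, and stay open. A chelator-specific response may be the source, as a hypothesis. The dose, the culture, the array design and the hybridisation differed together with the chelator and stay open.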

How the results depend on the processing

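All alternatives were planned before the data were examined except median signals on the dipyridyl array and the counts of called tRNA features. No called value changed direction among the loci named for ciclopirox olamine, phenanthroline and their difference, the tRNA features named above and the rRNA feature. The other called genes entered only the recomputed counts and correlations, so their directions were not checked one by one. The loci had been picked for the largest changes in the same data, so their kept direction is no measure for the other called genes. Of 161 recomputed counts and correlations that answer a comparison, 132 kept within 1.5 times the reported count or within the spread between arrays, and 29 moved. Of 667 other values, 564 kept their call and direction or, for values without a test and counts, stayed within the spread or 1.5 times, 79 of these untested values and counts moved further, 18 tested values lost and 6 gained a call, and 0 reversed. A kept call does not mean an unmoved value. The cause was not tested for any of the counts below except where the alternative sets a stricter or looser size or leaves out an array. At the methods' thresholds, the methods' t-test gave 132 higher and 47 lower genes with ciclopirox olamine, 130 and 61 with phenanthroline, 84 and 32 with both, and 38 that differed; after Benjamini-Hochberg adjustment 635 differed. At an adjusted p under 0.05 and at least 3-fold, the counts were 132 and 49, 130 and 62, and 84 and 33 with both. A dye coefficient gave 849 differing genes, in a fit whose spread was too small for some genes, so this count is not reliable. Leaving out each array in turn gave 419 to 677 higher and 340 to 554 lower genes with ciclopirox olamine, 409 to 478 and 429 to 482 with phenanthroline, 280 to 371 higher and 273 to 331 lower with both, 117 to 439 that differed, and r from 0.791 to 0.807. The lowest counts for ciclopirox olamine and for the difference came without ciclopirox olamine replicate 2, and the lone array left in a group is assumed to vary like the other chelator's. With dipyridyl, genes at least 3-fold lower numbered 4 from processed signals, 3 without background subtraction, 6 from the scanner's log ratios, 6 from the value table and 70 with median centring, and those at least 3-fold higher 14, 14 and 9 from the scanner's log ratios, the value table and median centring. At 2-fold the counts were 50 higher and 91 lower. A slide block was not run because all 4 dye-swapped arrays lie on 1 slide, and the alternatives for bile salt hydrolase and the gene lists were not run because no member was found. Aquantile leaves ratios unchanged by construction and the value table repeats the scanner's log ratios, so neither is an independent check in the tallies above. No paired analysis was possible because each array is itself a comparison of treated with untreated cells. No untreated probe was well above background for 4 genes with ciclopirox olamine and 11 with phenanthroline.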

Other observations

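The tests around Bbr_1635 were chosen after the result had been seen, and the other tests in this part were written before.

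With dipyridyl, genes around Bbr_1635, itself at a log2 ratio of -2.27, formed a long stretch of lower ratios. The 51 consecutive measured tags centred on it had a median log2 ratio of -0.51, with 36 below 0 and 15 at least 2-fold lower. The lowest median of any such window in 1000 shuffled gene orders was -0.37. Shuffling also removes the likeness of neighbouring tags, so this value does not show that the stretch stands apart from others. In the measured order it lay at percentile 1.41 of all windows, and the lowest window stood at -0.58. Among these 51 tags 27 were lower and 6 higher with phenanthroline (median -0.45), whereas 20 were lower and 18 higher with ciclopirox olamine (median 0.01). The phenanthroline median lay at percentile 2.61 of all windows, on arrays of another design, so the stretch may not be a feature of the single dipyridyl array. From the scanner's processed signals the dipyridyl median was -0.28, within the lowest shuffled value of -0.29. It lay below the lowest shuffled value without background subtraction (-0.31 against -0.26), from the scanner's log ratios (-0.46 against -0.31) and with median centring (-1.50 against -0.43). The whole stretch was picked from the same data, so that a common regulation of these genes is a hypothesis.

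Fold changes of neighbouring tags were more alike than in shuffled gene orders, with r of 0.423 or more for ciclopirox olamine and phenanthroline, and 0.379 for dipyridyl. A chance order of genes is unlikely as the source, and transcription in common units is a candidate explanation that the files give no table of units to test.

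A lower gene dosage near the first tag could produce a gradient along the tags in the same direction with ciclopirox olamine and phenanthroline. Spearman's rho between the fold change and the distance from tag 1 was -0.11 with ciclopirox olamine (circular shift permutation p = 0.38) and 0.0958 with phenanthroline (p = 0.0288), so these chelators shared no gradient. With dipyridyl rho was 0.197 on its 1 array, without a test. Phenanthroline and dipyridyl lay in the direction that a lower dosage would give, and such a gradient with these alone stays open. The p-values were not adjusted.

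Probe sequences of the dipyridyl design were read in the coding frame to ask whether genes with certain peptides moved together. The frame was checked on 5529 probes, of which 0 held a stop, against 6674 of 11058 other frames. Genes with a strongly hydrophobic stretch (127 genes) might have risen more than others, but their median differed from that of other genes by -0.00828 with ciclopirox olamine and -0.0323 with phenanthroline (permutation p = 0.94 and 0.552, adjusted 0.94 and 0.736). With dipyridyl, untested on 1 array, the difference was 0.231, so a rise with dipyridyl alone stays open. The 11 genes with a pair of cysteines spaced as in many metal sites, CxxC, might have fallen, but with ciclopirox olamine their median exceeded that of other genes by 1.36 (permutation p = 0.00013, adjusted 0.00052 over 4 tests), with 6 higher and 4 lower. With phenanthroline it exceeded it by 0.33 (permutation p = 0.141, adjusted 0.283), with 5 higher and 2 lower. With dipyridyl, untested, the difference was 0.215. The permutations drew genes as if they were independent, although neighbouring tags changed together, so small p-values here may be too small. Probes cover only part of each gene, so genes without a hit were not shown to lack the motif.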
